A study of Homo sapiens with 8 samples.

How the data were processed

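Poly(A)-selected RNA of PC3 cells, an established human prostate cancer line, was sequenced in 8 libraries, 4 labelled siCtrl and 4 labelled siPRMT7. Per the labels, cells were transfected with synthetic RNA by lipofection before harvest. The sample titles carry the prefix si, and the library names of the same samples carry the prefix sh. Groups were taken from the titles. The labels do not say whether the replicates came from separate cultures. No p-value therefore covers more than the spread between these samples, which can be technical.

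The deposited table holds FPKM values, fragments per kilobase of gene length and library size, for 58735 genes. The submitters' processing notes name cutadapt 2.5, HISAT2 2.1.0 and featureCounts 1.6.3. They also name a mouse genome build, which the table contradicts. All 58735 gene identifiers are human, and the start, end and strand of all 58735 match GENCODE release 29 on GRCh38. Coordinates are on that assembly. Whether counting used strand is not given in the sources used here, so exonic bases shared with a gene on the opposite strand are given for PRMT7. Overlaps of the other named genes were not checked.

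FPKM multiplied by gene length was a whole multiple of one step per library for 100% of the values above 0, within a tolerance of 0.01 fragments, so fragment counts were rebuilt. Totals ranged from 14526030 to 15724862 fragments. The library size behind each library's FPKM divided by its median-ratio size factor gave 15114523.93 in every library, which is the geometric mean of the totals. The deposited FPKM values were thus already scaled between libraries by median ratios. A floor of 3 fragments was used, 0.191 to 0.207 ppm of a library. Floors and counting bounds cover counting error only, and intervals from limma cover the spread between libraries.

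Genes with FPKM of at least 1 in at least 4 of the 8 libraries were tested, 13436 in all, of which 10934 were protein-coding. Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a variance trend and without robust estimation, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. PRMT7 was tested with a two-sided exact permutation test over 70 assignments, for which the smallest p is 0.0286. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 33 lists with at least 3 tested members. Camera compares the members of a list with the other genes. Its p-values thus also depend on the number of members and on the correlation used between them. Camera with an estimated correlation and fry, which asks whether a list moves one way without comparing it with other genes, were run beside it.

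The 34 gene lists, the tests, most alternatives and the rule for named genes were fixed before the data were examined. The lists held 930 entries, all of which matched a gene in the table. The rule took PRMT7 first, then up to 12 genes per direction with the largest log2 fold change among those that passed, with a symbol, a mean FPKM of at least 1 in both groups and no overlap between groups, leaving out pseudogenes and read-through genes. From each list described it took the 4 members with the smallest p, 6 for the S phase, G2/M phase, G1/S and CDK inhibitor lists, and allowed any member of the PRMT family.

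The alternatives were other pseudocounts, filters and scalings, other variance models, a replicate block, a fold-change threshold and leaving out each library. Count models planned for a table of raw counts were not run, because the table holds FPKM. Further alternatives were chosen after the data were seen: limma's voom on rebuilt fragments, a fragment filter, removal of each library's trend on gene length and GC content, the ribosomal protein level as a covariate, and protein-coding genes alone.

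The gene test was checked on simulated libraries with 200 changed genes, drawn for this comparison with 13478 genes in the test. It recovered 10.61% of the 1.2-fold changes, 63.64% of the 1.5-fold changes and 92.06% of the 2-fold changes that were tested. Of 115 genes called, 6 were unchanged ones. All genes were drawn with the same spread beyond counting noise (dispersion 0.00518), and no library was drawn as divergent. The recovery rates also depend on the number of genes changed, so they need not hold for the real libraries. A simulated log2 shift of 0.2 in the interferon list was recovered, and 0 of 32 unchanged lists were called. Genes were drawn independently of each other, whereas the estimated correlation within the real lists reached 0.854. The simulation thus cannot show how often camera calls unchanged lists whose members vary together.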

Results

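Transcript levels were measured by RNA sequencing in PC3 cells, a human prostate cancer line, in 4 libraries labelled siCtrl and 4 labelled siPRMT7. The series title concerns the arginine methyltransferase PRMT7, the cell cycle and progression of prostate cancer, so the comparison asks which transcripts differ when PRMT7 is targeted. Each library held 14526030 to 15724862 fragments. The chi-square per gene between pairs of libraries, which would be 1 from sampling noise alone, was 2.20 to 3.98 between siCtrl libraries and 3.03 to 22.6 between siPRMT7 libraries. The highest values involved siPRMT7 replicate 2, and without it the siPRMT7 pairs reached 5.49. That library lay at 28.4 on the first principal component, which held 31.4% of the variance, and the other 7 lay between -11.9 and 7.36. Ribosomal protein genes took 3.84% of its fragments, against 2.89 to 3.37% in the others.

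PRMT7, the targeted gene, was only slightly lower in the libraries labelled siPRMT7. PRMT7 (ENSG00000132600, chromosome 16, 68310974 to 68358563, plus strand) had 5.11 ± 0.183 FPKM in the siCtrl libraries and 4.69 ± 0.298 FPKM in the libraries labelled siPRMT7 (SD, n = 4 each). The mean was 8.29% lower, and the difference did not pass the exact permutation test (two-sided p = 0.0571, where the smallest possible is 0.0286). The log2 fold change was -0.10, with a 95% interval from -0.23 to 0.02 in limma, and a halving would have given -0.78. Between 612 and 788 fragments per library lay behind these values, a counting error of 4.04% at the lowest. In 3 of the 4 siPRMT7 libraries PRMT7 was below every siCtrl library. On the TPM scale, with every library brought to one total, the exact permutation p was 0.0286 and the log2 fold change -0.16, but that scaling also moved the median of all genes tested to -0.04. SMPD3 on the opposite strand shares 239 of the 9458 exonic bases of PRMT7, and the fragments within them are not known.

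**Figure D1:**
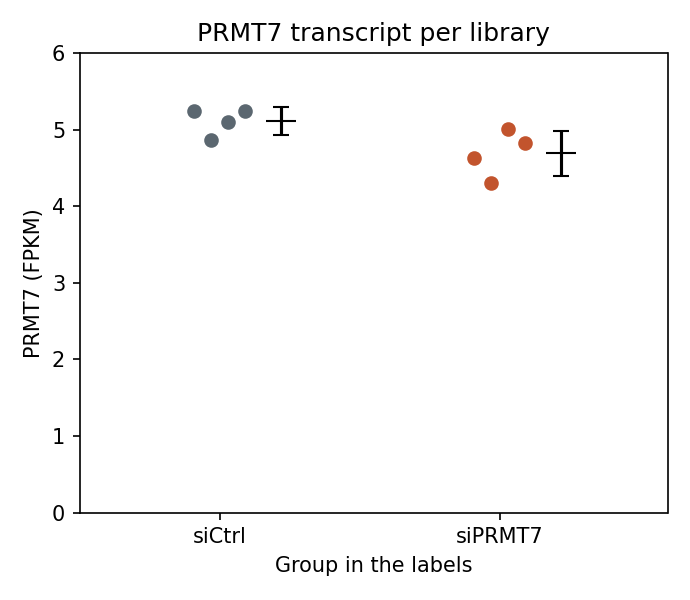
PRMT7 transcript level in FPKM (vertical axis, from 0) in each siCtrl and siPRMT7 library (points), with the group mean and SD (n = 4) beside the points. The siPRMT7 mean of 4.69 FPKM lies 8.29% below the siCtrl mean of 5.11 FPKM, and the groups overlap.

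In the libraries labelled siPRMT7, genes of the interferon response rose as a group and genes of S phase and of G2/M phase fell, all by small amounts. Of 42 interferon response genes 38 were higher, with a median log2 fold change of 0.21. Of 54 G2/M genes 50 were lower (median -0.13), and of 42 S phase genes 38 were lower (median -0.11). NF-kB target genes also rose, with 20 of 22 higher and a median of 0.19. Of the members of the gene lists, 1 interferon response gene was called over all genes tested, and 0 of any other list.

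Of 13436 genes tested with limma, 2 passed an adjusted p of 0.05, both higher in the siPRMT7 libraries. RSAD2 (ENSG00000134321, chromosome 2, 6865806 to 6898239, plus strand), which encodes the interferon-induced antiviral protein viperin, rose from 68.2 ± 0.939 to 99.5 ± 6.37 FPKM (SD, n = 4 each). Its ratio was 1.46, its log2 fold change 0.54 (SE 0.0498) and its adjusted p 0.0125, and all 4 siPRMT7 libraries lay above all 4 siCtrl libraries. Over the alternatives without pairing, the adjusted p of RSAD2 ran from 0.00121 to 0.112, and the call was lost with quantile normalization (0.052). It was also lost without siCtrl replicate 1, 2, 3 or 4 (adjusted p = 0.110, 0.112, 0.0989 and 0.0785) and without siPRMT7 replicate 1 or 3 (0.0559 and 0.0871). Without each of these 6 libraries 0 genes were called, and without siPRMT7 replicate 2 there were 2 higher. Without siPRMT7 replicate 4 there were 1 higher and 1 lower, the latter with at most 2 fragments in any library. The other call as reported, RNU7-140P, lies outside the naming rule and was singled out after its values were seen. This gene of 60 bases had 1 fragment in each siPRMT7 library and 0 in each siCtrl library, below the floor of 3 fragments, so no fold is given. With limma 0 genes were called lower as reported, against 12 with library weights, 3 with the ribosomal protein covariate, 2 with no filter, 1 with voom on rebuilt fragments and 2 with voom at 10 fragments. The 2 lower with no filter had at most 1 fragment in any library, under that floor. At an unadjusted p under 0.05 there were 1769 genes, 1031 higher and 738 lower, where 671.8 would pass with no effect. That count was 2754 without siPRMT7 replicate 1 and 1166 without siCtrl replicate 4. The groups did not overlap for 8.57% of genes, against 2.86% by chance. With voom 12 genes were called in all, and with library weights 58, of which 46 were higher.

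The interferon response list had the smallest camera p of the 33 lists (adjusted p = 1.30e-20, and adjusted p = 0.00721 with an estimated correlation). Over all genes tested 1 member was called, and 30 passed when adjusted over the list alone, all higher. That count was 22 to 31 without 1 library and 19 with quantile normalization. TRIM22, an interferon-induced antiviral protein, had 4.21 ± 0.156 FPKM in siCtrl and 5.88 ± 0.260 FPKM in siPRMT7 libraries (log2 fold change 0.40, limma adjusted p = 0.000368 over the list alone). OASL, an oligoadenylate synthetase relative induced by interferon, had 203 ± 8.71 and 259 ± 8.86 FPKM (0.35, limma adjusted p = 0.00064 over the list alone). CMPK2, a mitochondrial nucleotide kinase, had 27.3 ± 0.622 and 36.5 ± 3.27 FPKM (0.40, limma adjusted p = 0.000936 over the list alone). In all 3 the siPRMT7 libraries lay above every siCtrl library. Over all genes the limma adjusted p was 0.0735 for TRIM22 and 0.101 for OASL and CMPK2, and 0.0408 for CMPK2 without siPRMT7 replicate 2. All 3 passed over all genes with library weights (0.0258 each), voom, the ribosomal protein covariate and protein-coding genes alone. TRIM22 and OASL also passed with the length and GC trend removed (0.025 and 0.039), and OASL on the TPM scale (0.0448). The mean level of the list was 0.192 to 0.247 above the siCtrl mean in the siPRMT7 libraries, and the siCtrl libraries lay from -0.0166 to 0.0114.

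Genes of NF-kB signalling rose as well. For the NF-kB targets the adjusted p was 3.80e-08 (adjusted p = 0.0163 with an estimated correlation), and 7 members passed when adjusted over the list alone (5 to 9 without 1 library, 4 on the TPM scale). TNFAIP3, an inhibitor of NF-kB signalling, had 15.4 ± 0.294 and 17.8 ± 0.520 FPKM in siCtrl and siPRMT7 libraries. The chemokine CXCL8 had 80.3 ± 3.32 and 98.97 ± 11.1 FPKM, and CXCL2 had 10.3 ± 0.735 and 13.2 ± 1.40 FPKM. Of 24 immediate early genes 19 were higher (median 0.08, adjusted p = 4.95e-05, and adjusted p = 0.132 with an estimated correlation). Adjusted over the list alone 11 passed, but 3 without siCtrl replicate 4 or siPRMT7 replicate 3, 5 without siCtrl replicate 1 or 3 or siPRMT7 replicate 4, and 7 without siCtrl replicate 2. On the TPM scale or with quantile normalization that count was 4, and the median was 0.14 with FPKM at least 5. JUNB, a subunit of the AP-1 transcription factor, had 82.7 ± 5.34 and 105 ± 9.34 FPKM, and ATF3 had 36.5 ± 1.43 and 43.2 ± 1.73 FPKM.

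Genes of G2/M phase, S phase and DNA repair fell. For G2/M genes the adjusted p was 1.14e-13 (adjusted p = 0.00853 with an estimated correlation), and 17 members, all lower, passed when adjusted over the list alone. That count fell to 7 without siCtrl replicate 2 or 4 or siPRMT7 replicate 3, to 8 without siCtrl replicate 3 and to 9 without siPRMT7 replicate 4. ANLN, an actin-binding protein of cytokinesis, had 18.5 ± 0.703 FPKM in siCtrl and 14.8 ± 0.674 FPKM in siPRMT7 libraries, a log2 fold change of -0.30. The mitotic kinesin KIF11 had 7.04 ± 0.364 and 5.51 ± 0.213 FPKM (-0.31), and DNA topoisomerase TOP2A had 12.01 ± 0.334 and 9.22 ± 0.893 FPKM (-0.35). TPX2, a spindle assembly factor, had 43.4 ± 0.727 and 37.1 ± 1.35 FPKM (-0.22). Each of these 4 was lower in every siPRMT7 library than in any siCtrl library, with an adjusted p of 0.00468 over the list alone. For S phase genes the adjusted p was 2.15e-08 (adjusted p = 0.0247 with an estimated correlation), and 6 members passed when adjusted over the list alone. That count was 0 without siCtrl replicate 1 or 3 or siPRMT7 replicate 4, 1 without siPRMT7 replicate 3, 2 without siCtrl replicate 2, 3 without siPRMT7 replicate 1 and 13 without siPRMT7 replicate 2. Over the other settings, pairing apart, it ran from 3 to 17. The S phase median was -0.16 on the TPM scale. RRM1, a subunit of ribonucleotide reductase, had 20.6 ± 0.577 and 17.6 ± 0.784 FPKM (-0.22), and DTL had 11.5 ± 0.241 and 9.22 ± 0.818 FPKM (-0.30). DNA repair genes fell too, with 27 of 39 lower (median -0.07, adjusted p = 0.00106, and adjusted p = 0.0352 with an estimated correlation). The median of that list was -0.03 with FPKM at least 5 (adjusted p = 0.0458), -0.04 with library weights or with the length and GC trend removed, -0.05 with no filter and -0.11 on the TPM scale. In that list BARD1, the partner of BRCA1, had 2.78 ± 0.194 and 2.102 ± 0.0739 FPKM (limma adjusted p = 0.0475 over the list alone). It was the 1 member that passed, and 0 passed without any 1 of the 8 libraries, where the value for BARD1 was 0.0605 to 0.187. Over the other settings, pairing apart, 0 to 4 members passed. BARD1 did not pass with no filter (0.0507), with the length and GC trend removed (0.0544) or with the ribosomal protein covariate (0.0796).

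**Figure D2:**
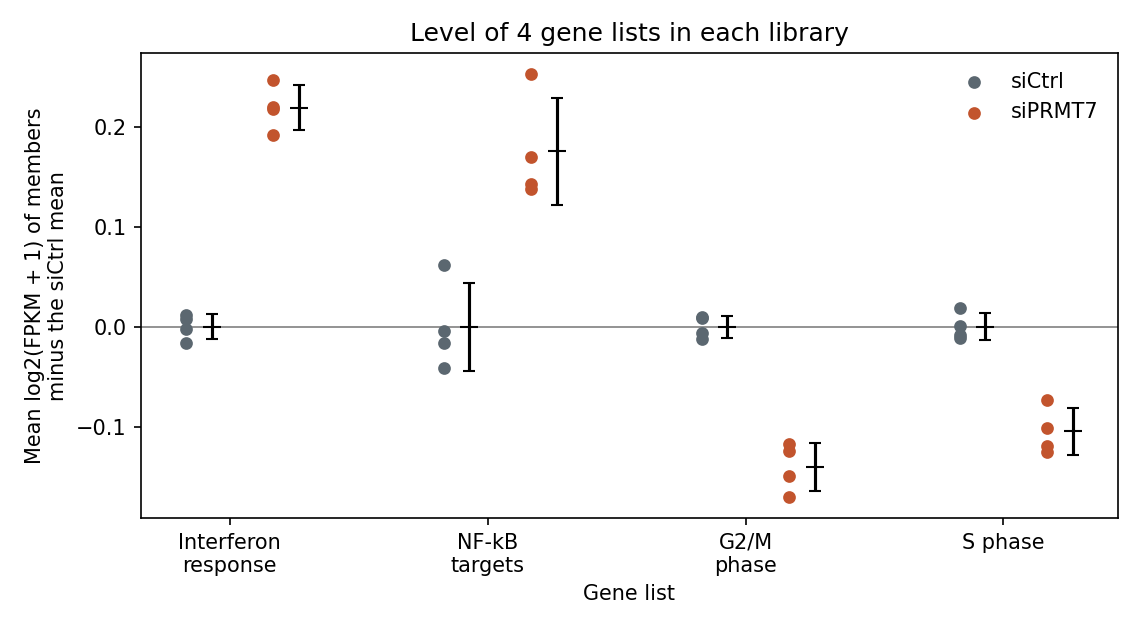
Mean log2(FPKM + 1) of the tested members of 4 gene lists in each library (points), minus the siCtrl mean of that list, with the group mean and SD (n = 4) beside the points. The siPRMT7 libraries lie from 0.192 to 0.247 for the interferon response and from -0.171 to -0.118 for G2/M phase, apart from the siCtrl libraries in both.

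At the preset correlation, regulators of G1 and the G1 to S transition fell and CDK inhibitors rose. Of 23 G1 and G1/S regulators 17 were lower (median -0.07, adjusted p = 0.0192), and 0 passed when adjusted over the list alone. The adjusted p was 0.132 with an estimated correlation, 0.110 without siPRMT7 replicate 1 and 0.0797 with a filter of FPKM at least 5, and it ran from 0.00337 to 0.110 over the left-out libraries. The median was -0.12 on the TPM scale and -0.04 without siPRMT7 replicate 4. Of 8 CDK inhibitors 7 were higher (median 0.19, adjusted p = 0.00182, and adjusted p = 0.227 with an estimated correlation), and 3 passed when adjusted over the list alone. That count was 1 without siCtrl replicate 1 or 2 or siPRMT7 replicate 2, 3 or 4, and 5 without siCtrl replicate 3. Over the other settings, pairing apart, it ran from 1 to 5. The adjusted p was 0.0635 by fry and 0.0516 with the ribosomal protein level as covariate. CDKN1A, which encodes p21, had 23.2 ± 0.325 FPKM in siCtrl and 27.7 ± 1.59 FPKM in siPRMT7 libraries (log2 fold change 0.25, limma adjusted p = 0.00371 over the list alone). CDKN2A had 39.3 ± 2.29 and 49.0 ± 7.12 FPKM, and CDKN1C had 2.33 ± 0.365 and 3.13 ± 0.268 FPKM.

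Further lists passed camera and lost the call with an estimated correlation. Higher were p53 targets (14 of 19, adjusted p = 0.0101, and adjusted p = 0.119 with an estimated correlation) and apoptosis regulators (19 of 22, 0.00965 and 0.208). Cholesterol genes (19 of 25, 0.000523 and 0.132), integrated stress response genes (19 of 26, 0.00876 and 0.310) and replication-dependent histones (19 of 25, 0.00198 and 0.310) were also higher, and the values are given in the same order. Adjusted over the list alone, 2 p53 targets, 0 apoptosis regulators, 2 cholesterol genes and 3 histone genes passed, all higher, as did 5 stress response genes higher and 1 lower. Without 1 library these counts ran from 1 to 5 for p53 targets (5 without siPRMT7 replicate 1, and 1 without siCtrl replicate 1, 2 or 4 or siPRMT7 replicate 2, 3 or 4) and from 2 to 4 for histones. Of apoptosis regulators 3 passed without siPRMT7 replicate 1 and 2 without siPRMT7 replicate 2. Of cholesterol genes 0 passed without any siCtrl library or without siPRMT7 replicate 3 or 4. Over the other settings, pairing apart, 0 to 2 cholesterol genes passed. Of stress response genes 2 passed without siCtrl replicate 1, 2 or 4 or siPRMT7 replicate 3. The stress response call was lost by quantile normalization (0.223) and fry (0.0641). The histone call was lost by fry (0.113), with the length and GC trend removed (0.0680) and with the ribosomal protein covariate (0.0839). Histone genes are near-identical copies, and poly(A) selection captures replication-dependent histone transcripts poorly, so their values are uncertain. PPP1R15A, a phosphatase regulator of the stress response, had 98.96 ± 3.21 FPKM in siCtrl and 126 ± 6.90 FPKM in siPRMT7 libraries. Among hypoxia and glycolysis genes 21 of 28 were higher, with an adjusted p of 0.0280 and an adjusted p of 0.212 with an estimated correlation. It had 0 members passing over the list alone (1 without siPRMT7 replicate 1 or 2), and its adjusted p reached 0.731 with quantile normalization, 0.178 on the TPM scale, 0.164 with FPKM at least 5 and 0.1001 with the ribosomal protein covariate. That call was lost without siCtrl replicate 1 or 2 (0.0623 and 0.0815) and without siPRMT7 replicate 3 or 4 (0.0625 and 0.0601). Adhesion and motility genes were lower in 20 of 27 (adjusted p = 0.0396, and adjusted p = 0.302 with an estimated correlation). In it 1 gene higher and 1 lower passed over the list alone, but 0 without siCtrl replicate 2, 3 or 4 or siPRMT7 replicate 3 or 4 and 1 without siPRMT7 replicate 2. The call was lost with the ribosomal protein covariate (0.188), voom at 10 fragments (0.1696), no filter (0.139), library weights (0.0812), FPKM at least 5 (0.0654), protein-coding genes alone (0.0515) and by fry (0.144). It was also lost without siCtrl replicate 3 or 4 (0.0910 and 0.0788) and without siPRMT7 replicate 2 (0.102).

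Ribosomal protein and nuclear respiratory chain genes were higher and mitochondrially encoded genes lower at the preset correlation alone. Cytosolic ribosomal protein genes were higher in 73 of 75 (adjusted p = 1.37e-08), with 0 passing over the list alone (18 without siPRMT7 replicate 1) and an adjusted p of 0.586 with an estimated correlation. Their share of fragments was 3.01 ± 0.113% in siCtrl and 3.30 ± 0.409% in siPRMT7 libraries (SD, n = 4 each, exact permutation p = 0.257), and 3.12% without siPRMT7 replicate 2. Nuclear-encoded oxidative phosphorylation genes were higher in 36 of 41 (adjusted p = 0.00114, and adjusted p = 0.657 with an estimated correlation). The adjusted p was 0.257 without siPRMT7 replicate 2, and with the ribosomal protein covariate the direction turned to lower (0.779). The ribosomal protein list itself had 0.798 with that covariate, which is built from its own members. By fry the adjusted p was 0.413 for ribosomal protein, 0.474 for respiratory chain and 0.157 for mitochondrially encoded genes. Adjusted over the list alone, 0 members of the respiratory chain and mitochondrially encoded lists passed, against 1 respiratory chain gene without siPRMT7 replicate 1 and 1 mitochondrially encoded gene without siCtrl replicate 1. For mitochondrially encoded genes that count was 7 with voom and 6 on the TPM scale or with quantile normalization. All 13 mitochondrially encoded genes were lower (median -0.20, adjusted p = 4.95e-05, and adjusted p = 0.365 with an estimated correlation), with a median of -0.12 without siCtrl replicate 4. Their chromosome took 2.29 ± 0.275% of fragments in siCtrl and 2.005 ± 0.0973% in siPRMT7 libraries (exact permutation p = 0.0571).

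**Figure D3:**
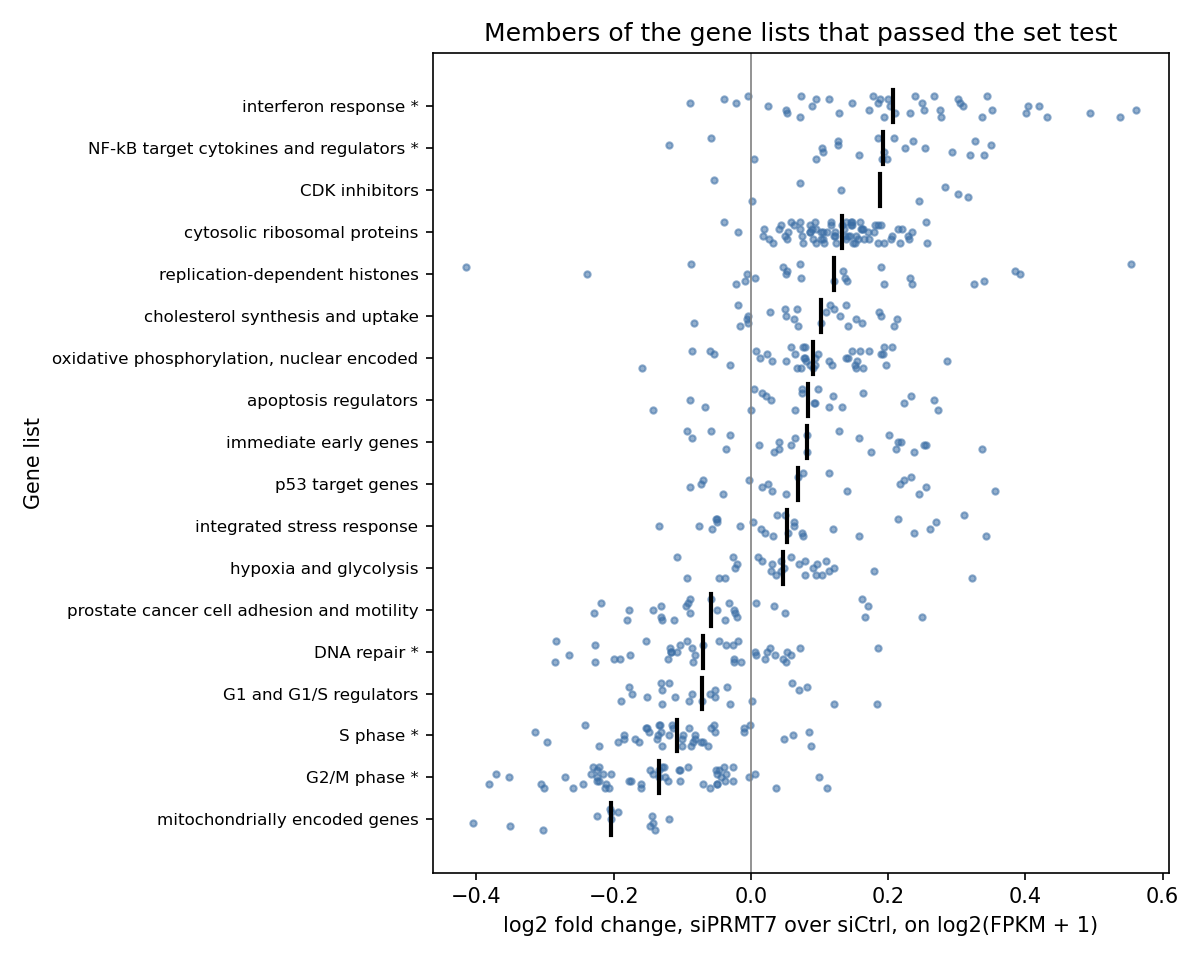
Log2 fold change of each tested member (points) of the 18 gene lists that passed camera, with the list median as a bar, and an asterisk where the call holds with an estimated correlation. The medians run from -0.20 for mitochondrially encoded genes to 0.21 for the interferon response, and 5 lists carry an asterisk.

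The other 15 lists tested did not pass. For the prostate and cell-state lists, the adjusted p was 0.0996 for epithelial, 0.733 for mesenchymal, 0.954 for androgen receptor target and luminal, 0.208 for basal and 0.642 for neuroendocrine genes. It was 0.411 for fibroblast genes, and of 16 blood and endothelial genes 1 was expressed enough to test. Matrix proteolysis genes had an adjusted p of 0.0547, WNT and planar polarity genes 0.554 and TGF-beta targets 0.890. For the stress and metabolic lists the value was 0.411 for ER chaperones, 0.838 for heat shock proteins and 0.890 for fatty acid synthesis. It was 0.196 for Sm proteins and splicing factors, 0.890 for MYC targets of ribosome biogenesis and 0.890 for the PRMT family. Adjusted over the list alone, 1 basal gene, 1 fatty acid gene and, of TGF-beta targets, 1 higher and 1 lower passed. Without 1 library these counts ran from 0 to 1 for basal genes (0 without siCtrl replicate 2), 0 to 2 for fatty acid genes (0 without any siCtrl library or siPRMT7 replicate 3 or 4, and 2 without siPRMT7 replicate 2) and 0 to 4 for TGF-beta targets (0 without siCtrl replicate 1, 2 or 4 or siPRMT7 replicate 3 or 4, 1 without siCtrl replicate 3, and 4 without siPRMT7 replicate 1). Of the other lists that did not pass, with 0 as reported, 3 mesenchymal and 3 ER chaperone genes passed without siPRMT7 replicate 1. Without siPRMT7 replicate 2 it was 2 neuroendocrine genes, 1 mesenchymal gene and 1 androgen receptor target or luminal gene. Over the other settings, pairing apart, up to 4 mesenchymal, 3 neuroendocrine, 2 matrix proteolysis, 2 heat shock and 1 androgen receptor target or luminal genes passed. Median, mean and test differed in sign for the PRMT family, heat shock, fatty acid and ribosome biogenesis lists. Matrix proteolysis genes passed without siCtrl replicate 3 (0.0217) or siPRMT7 replicate 1 (0.0493), epithelial genes without siCtrl replicate 4 (0.0491), and splicing factors without siPRMT7 replicate 1 (0.0232). Matrix proteolysis genes also passed with library weights (0.0444), voom (0.0422), voom at 10 fragments (0.0214) and protein-coding genes alone (0.0463), and splicing factors with the length and GC trend removed (0.0409).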

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

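The tests on interferon transcripts, on swapped labels and on the gene overlapping PRMT7 were chosen after the result was seen, and the fits with the length and GC trend removed and with the ribosomal protein covariate were added after the data were seen. Of 234 groups of 4 values checked for a library far from the other 3, 11 held one, and chance gives about 1 in 20, or 11.7. Of the 11, 3 were in siPRMT7 replicate 2.

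The ribosomal protein share of siCtrl replicate 3 was 3.17%, against 2.94 to 2.96% in the other siCtrl libraries, and its FAU level was 149 FPKM against 133 to 134. CXCL8 in the same library was 85.3 FPKM against 78.2 to 79.0. In siCtrl replicate 4, ATAD2 was 13.5 FPKM against 12.5 to 12.6 and CXCL2 was 9.24 against 10.7. BAD in siCtrl replicate 2 was 18.6 FPKM against 22.1 to 22.3. In siPRMT7 replicate 2, RRM1 was 18.7 FPKM against 17.0 to 17.3, FANCI 5.2 against 6.63 to 6.70, and HIST2H2AA3 8.37 against 5.86 to 6.18. In siPRMT7 replicate 1, PPP1R15A was 116 FPKM against 129 to 130, and INSIG1 17.1 against 18.1 to 18.3.

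Interferon response genes were higher in the siPRMT7 libraries. One divergent library as the whole cause is argued against, since the list median stayed at 0.197 (adjusted p = 9.53e-27) without siPRMT7 replicate 2. A trend on gene length or GC content is argued against by a median of 0.206 after its removal, and a shift in RNA composition followed by ribosomal protein genes by a median of 0.194 with the ribosomal protein level as covariate. An innate response to the transfected RNA that differs between the arms stays open and cannot be told apart from an effect of PRMT7, because the arms differ in the transfected RNA. Interferon transcripts were present in every library, with at least 117 fragments of IFNB1, so the response may have been active in both arms.

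G2/M phase genes were lower in the siPRMT7 libraries. The median was -0.147 without siPRMT7 replicate 2, -0.130 after removal of the length and GC trend and -0.156 with the ribosomal protein covariate, which argues against each of these as the whole cause. A biological difference between the arms is a hypothesis that these tests leave open, and an effect of the transfected RNA unrelated to PRMT7 was not tested for this list.

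The PRMT7 transcript was only slightly lower in the siPRMT7 libraries. Swapped labels hiding a strong knockdown are argued against, since the lowest library was at 0.821 of the highest (lower counting bound 0.757). Reads of SMPD3, which had 129 to 209 fragments per library and shares 2.53% of PRMT7's exonic bases, stay open as a source of PRMT7 fragments, because the table does not give the fragments within the shared bases. Recovery of the transcript by the time of harvest, or a weak reagent, was not tested.

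Other splits of the 8 libraries into 4 and 4 were fitted, 35 in all. As many genes as the 2 called were found in 2 of the 35 splits, the real one included, and the highest other split called 2, so chance is not excluded for the count of genes. For the 18 lists called, 1 of 35 splits gave as many, the highest other being 15. That is the smallest share 35 splits can give, so it argues against chance there but does not exclude it. The real split alone gave as small a p for the interferon response (3.94e-22, the smallest other 5.76e-13), G2/M phase (6.90e-15 and 3.29e-10) and NF-kB targets (5.76e-09 and 2.02e-07). The same held for S phase (2.60e-09 and 3.04e-09) and DNA repair (0.000289 and 0.000682), by little. In 18 of the other splits 2 libraries of each group lay on both sides, and the rest kept 3 libraries of a group together. In those 18, at most 6 lists and 1 gene were called, and the smallest unadjusted camera p was 0.0906 for the interferon response, 0.0443 for G2/M phase and 0.0516 for S phase.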

How the results depend on the processing

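The fits with voom, with a fragment minimum, with the length and GC trend removed, with the ribosomal protein covariate and with protein-coding genes alone were chosen after the data were seen, as was the class I list. Of 891 list tests under the alternatives, 791 kept direction and side of the threshold, 47 were no longer called, 9 were newly called and 44 changed direction, of which 1 was called as reported and 0 under the alternative. Interferon response (adjusted p from 1.26e-32 to 2.63e-13), G2/M phase (7.59e-21 to 1.61e-08) and S phase (1.47e-11 to 1.44e-05) were called in all 25 other gene fits. These ranges are from camera at the preset correlation, and the estimated correlation was not combined with those fits. Of the genes the naming rule selects from lists that passed, and those named among the other observations, 86 in all and not all named in the text, each kept its direction in all 2145 values. Some not called as reported passed over all genes: 18 with library weights, 8 with the ribosomal protein covariate, 5 with voom at either filter, 4 with protein-coding genes alone, 3 with the length and GC trend removed, 1 on the TPM scale and 1 (CMPK2) without siPRMT7 replicate 2. Of the 137 genes the naming rule selects, lists that did not pass included, 9 changed direction in 30 of 3405 values, and the restriction to the former was made after those changes were seen. The cause was not tested for any change here unless stated. Count models in DESeq2 and edgeR were planned only for a table of raw counts, and they were not run on the rebuilt fragments. On simulated libraries at this depth and number, 10.61% of 1.2-fold changes were recovered, and what limits this was not tested. Those libraries had the same dispersion for all genes and no divergent library, so the rate need not hold for the real ones.

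The number of genes called, 2 as reported, was 1 (higher) with a pseudocount of 0.1 or 0.01, with FPKM at least 5, with quantile normalization and with at least 10 fragments. It was 5 with no filter (2 lower), and of these all but RSAD2 had at most 1 fragment in any library. The number was 58 with library weights (46 higher, 12 lower), 12 with voom (11 higher, 1 lower) and 15 with voom at 10 fragments (13 higher, 2 lower). It was 8 (all higher) with the length and GC trend removed, 26 (23 higher, 3 lower) with the ribosomal protein covariate and 11 (all higher) with protein-coding genes alone, where fewer genes are tested. With an absolute log2 fold change of at least 1 it was 1, which is RNU7-140P with 1 fragment against 0, so 0 genes above the floor of 3 fragments met it. Leaving out 1 library gave 0 to 2 genes, 0 to 2 higher and 0 to 1 lower, the lower one with at most 2 fragments in any library. Lists called, 18 as reported, numbered 5 with an estimated correlation, 11 by fry, 12 with the ribosomal protein covariate and 16 to 19 over the left-out libraries. For PRMT7 the log2 fold change was -0.16 on the TPM scale (exact permutation p = 0.0286), where the median of all genes tested was -0.04, and -0.13 to -0.07 without 1 library.

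G1 and G1/S regulators had an adjusted p of 0.0797 with FPKM at least 5, 0.132 with an estimated correlation and 0.00337 to 0.110 without 1 library. CDK inhibitors had 0.227 with an estimated correlation, 0.0635 by fry, 0.0516 with the ribosomal protein covariate and 0.00102 to 0.0192 without 1 library. With that covariate nuclear oxidative phosphorylation genes turned to lower (0.779).

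Lists that did not pass changed direction as follows, with adjusted p. With no filter these were the PRMT family (0.993), androgen receptor targets (0.786) and ribosome biogenesis (0.993). With FPKM at least 5 they were androgen receptor targets (0.651) and TGF-beta targets (0.915). On the TPM scale they were heat shock (0.509), fatty acid (0.862) and TGF-beta genes (0.999). With quantile normalization they were ER chaperones, fatty acid and TGF-beta genes (0.716 each), heat shock (0.132) and splicing factors (0.900). With library weights they were the PRMT family and heat shock (0.840 each) and androgen receptor targets (0.986). With voom they were fatty acid genes (0.936), and mesenchymal genes (0.947) at 10 fragments. With the length and GC trend removed they were androgen receptor targets (0.909) and heat shock (0.497). With the ribosomal protein covariate they were mesenchymal (0.685), androgen receptor (0.940), fibroblast (0.785), ER chaperone (0.798), heat shock (0.1001), splicing factor (0.0724) and TGF-beta genes (0.956). For lists that turned without 1 library, ranges over every such fit, turned or not, are as follows. They ran from 0.613 to 0.985 for the PRMT family, 0.428 to 0.870 for mesenchymal and 0.806 to 0.993 for androgen receptor genes. Those of heat shock ran from 0.418 to 0.985 and of fatty acid genes from 0.172 to 0.985. They ran from 0.0232 to 0.563 for splicing factors, 0.190 to 0.993 for ribosome biogenesis and 0.589 to 0.993 for TGF-beta targets. The 0.0232 of splicing factors was in the reported direction. Where direction turned, values were 0.806 to 0.985 for the PRMT family and 0.909 to 0.985 for androgen receptor genes. They were 0.418 to 0.985 for heat shock, 0.816 to 0.934 for fatty acid and 0.783 to 0.993 for ribosome biogenesis genes. Mesenchymal genes turned at 0.870, splicing factors at 0.563 and TGF-beta targets at 0.960.

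With a replicate block 0 genes were called, 0 of them higher, and RSAD2 had an adjusted p of 0.142. Fatty acid genes turned direction (0.957), and hypoxia (0.0565) and adhesion genes (0.0620) were no longer called. For PRMT7 the exact sign-flip p was 0.125, the smallest 4 differences can give. The values showed no effect shared by same-numbered libraries. Their correlations, with each group's mean subtracted, were -0.0314, -0.0133, 0.0451 and 0.0613. Of the 4 siCtrl libraries, 0 correlated best with its own number. Samples prepared in pairs without a shared effect would give the same, so pairing is not excluded.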

Other observations

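The list of class I antigen presentation genes and its tests were chosen after the data were seen. Genes of this pathway, which loads peptides on HLA molecules at the cell surface, were compared between the groups. Of 21 genes tested 18 had a higher mean in the siPRMT7 libraries (median log2 fold change 0.18), 10 passed when adjusted over the list alone, and 0 were called over all genes. TAP1, a peptide transporter, had 26.8 ± 0.822 FPKM in siCtrl and 32.0 ± 0.533 FPKM in siPRMT7 libraries. HLA-B had 69.4 ± 2.56 and 95.5 ± 11.8 FPKM, and HLA-C had 200.4 ± 12.02 and 264.8 ± 27.6 FPKM, though reads of HLA genes can be shared between copies. B2M, the light chain of these molecules, had 526 ± 24.4 and 632 ± 64.1 FPKM. The camera p was 0.018 with an estimated correlation, and 1 of 35 splits gave as small a p at the preset correlation (1.21e-08, the smallest other 2.96e-05). Because the genes were chosen after the data were seen, these values cannot show that the list is higher as a group. None of its members is on the interferon list, but many are known to be induced by interferon, so it is not independent of that pattern. Over the other settings its median ran from 0.116 to 0.208.

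Interferon-induced transcripts were already abundant in the siCtrl libraries. IFI6 ranked 4 and ISG15 ranked 5 among all genes by mean siCtrl level, at 2511 ± 115 and 2473 ± 75.0 FPKM. In the siPRMT7 libraries they were at 3191 ± 461 and 3090 ± 472 FPKM. IFNB1 was at 10.2 ± 1.196 FPKM in siCtrl and 12.2 ± 1.42 FPKM in siPRMT7 libraries, and IFNL1 at 6.22 ± 0.934 and 9.29 ± 2.26 FPKM. No untransfected library was analysed here, so the level before transfection is unknown.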
